A study of Gemmatimonas phototrophica with 24 samples.

How the data were processed

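Transcripts of Gemmatimonas phototrophica AP64 were measured by RNA sequencing in 24 libraries. Per the labels' protocols, cultures of 100 mL were started at an optical density (600 nm) near 0.03, grown aerobically in the dark, and at about 0.2 exposed to light of 200 µmol photons per square metre and second for 2, 4 or 8 h, while others are labelled dark at the same times. Ribosomal RNA was depleted with a RiboZero kit, and the libraries were read from both ends on an Illumina NovaSeq instrument over 100 cycles, per the labels' protocols. Groups were taken from the sample titles. Sample numbers in the titles run from 1 to 6, of which 1 to 3 recur in the libraries labelled light and 4 to 6 in those labelled dark, and the labels do not say that a number marks one culture. Light and dark libraries of 1 time share no sample number. Of the comparisons made, only dark at 2 h against 0 h had every pair of libraries with the same sample number correlated above 0.1 in their deviations from the group means (0.127 to 0.515, 3 pairs), so a block by that number is given beside its results where it moves a count by over 1.5 times, and otherwise with the alternatives. Groups and labels were used as given throughout, and no library was moved to another group.

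The deposited values are raw counts per locus, made by the authors with featureCounts 2.0.1 per the file headers, on assembly ASM69509v2 of the strain. Per the same headers, read pairs were counted on the reverse strand over protein-coding, ribosomal RNA, transfer RNA and transfer-messenger RNA loci, and reads that mapped to several places or overlapped several loci were counted at each of them. Genes with near-identical copies, and overlapping neighbours, therefore share counts. Bowtie2 and edgeR are named in the submitters' processing notes, with versions not given in the sources used here. Of 3970 loci, 3926 matched a RefSeq table of the same assembly by locus tag and 44 did not. That table gave a symbol for 609 loci and no product names, so most loci could be named only by their tag. Where several loci share a symbol, which was so for 70 of the loci, the tag follows the symbol. Coordinates are those of the deposited files, 1-based on ASM69509v2.

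All tests were run in R 4.3.3 on the deposited counts. The main test was the quasi-likelihood test of edgeR 4.0.16, with TMM scaling and edgeR's default filter on low counts, which left 3963 loci and removed 7. Robust fits had 1 term per group over all 24 libraries, and each two-sided test was adjusted by Benjamini-Hochberg over the loci tested, with a threshold of 0.05. The common biological coefficient of variation was 17.9%. CPM values, counts scaled to library size, used the same scaling. The comparisons were light minus dark at 2, 4 and 8 h, the differences between these, dark at 8 h minus 0 h, and 0 h libraries 1 to 3 minus 4 to 6. Comparisons of each light or dark group with 0 h were added after the positions of the groups had been seen. The groups, comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. In that rule, each light minus dark comparison names the 6 highest and 6 lowest genes past the threshold with a symbol, a mean of at least 10 CPM and all 3 light libraries on one side of all 3 dark libraries, the 2 members of each list with the smallest p, and a fixed set of photosynthesis, stress and repair genes. It names 4 and 4 genes for dark at 8 h minus 0 h, and 3 and 3 for each difference between times. Other genes named were chosen after their values were seen.

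Of 22 fixed gene lists, matched on symbols, the 16 with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals. The lists for carotenoid synthesis and for transposases had 0 members by symbol and gave no result, because the names available were symbols alone. Those for photoreceptors and light-linked regulators, for sigma factors and for iron uptake had 1 member each. The list of ribosomal and transfer RNA, a sign of RNA quality, had 3 members and was only counted. Overlaps between times were set against the overlap of independent lists.

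The alternatives were RLE scaling, library totals with no factor, no filter on low counts, counts without ribosomal and transfer RNA, blocks by replicate or sample number, fits to the groups compared alone, DESeq2 1.42.0, an added threshold of 1 on the log2 fold change, a prior count of 0.5, fry in place of camera, and leaving out each library in turn. Leaving out together the 3 libraries that stood apart from their groups was added after seeing the data. The steps were tested on simulated counts with known changes. In a simulation of the 2 h comparison with 3958 genes, edgeR recovered 18 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 3 of its 144 calls were of unchanged genes. Most changes of 1.5-fold were thus missed in that simulation. It held far fewer calls than the 747 of the data at 2 h, so its adjusted threshold was stricter. The share missed there therefore does not set what the data could detect. In the same simulation DESeq2 recovered 19 of 67, 57 of 67 and 66 of 66, with 7 of 149 calls on unchanged genes, and with no change simulated edgeR called 1 gene at 2 h. Simulated libraries were drawn independently, with no difference between sample numbers and the same spread for a gene in every group. The few calls on unchanged genes therefore do not cover false calls that such structure could give in the data.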

Results

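Gemmatimonas phototrophica is an aerobic heterotrophic bacterium that builds a bacteriochlorophyll-based photosystem. Its strain AP64 was grown in the dark at 25 °C, and RNA was sequenced from dark-adapted cells and from cultures then kept in light or in the dark. Each time thus has a dark-labelled group to set against light, although light and dark libraries share no sample number. A difference between these sets of cultures that arose after 0 h cannot be told apart from a response to illumination. The 24 libraries fell into 7 groups, with 6 libraries of dark-adapted cells at 0 h and 3 libraries each labelled light or dark at 2, 4 and 8 h. The libraries held a median of 11.3 M counts (M, mega), from 2.97 M in dark 8 h replicate 2 to 49.1 M in dark 8 h replicate 3. Ribosomal RNA took 63.0% to 74.5% of the counts and the transfer-messenger RNA 3.72% to 8.56%, which left 0.667 to 11.6 M protein-coding counts per library. The ribosomal RNA share was 68.0% ± 2.34 (SD, n = 3) in the libraries labelled light and 70.6% ± 2.58 in those labelled dark at 2 h, 69.5% ± 0.716 and 71.1% ± 3.65 at 4 h, and 67.3% ± 3.79 and 72.0% ± 0.638 at 8 h. None of these differences passed a two-sided exact permutation test (p = 0.3, 0.5 and 0.1), in which 3 libraries against 3 cannot give a p below 0.1. The labels speak of triplicate cultures, and no replicate pair agreed within sampling noise, with a chi-square per degree of freedom of 3.95 to 152 over 33 pairs.

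The libraries labelled light lay close to the 0 h libraries, and the libraries labelled dark at 2, 4 and 8 h lay apart from both. On the first principal component of log2 CPM (counts scaled to library size), with 30.1% of the variance, the libraries labelled dark had scores of 10.2 to 21.6 and those labelled light at 2 and 4 h of -13.7 to -10.5. The 0 h libraries numbered 1 to 3, the numbers that recur in the light series, scored -12.9 to -12.1, and those numbered 4 to 6, the numbers that recur in the dark series, -3.55 to -0.26. Light 8 h replicate 2 scored -0.69, away from -7.43 and -7.61 for the other light libraries of that time. On the second component, with 18.2% of the variance, dark 4 h replicate 1 scored -19.4 and dark 8 h replicate 1 scored -28.3, away from the other libraries of their groups.

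**Figure D1:**
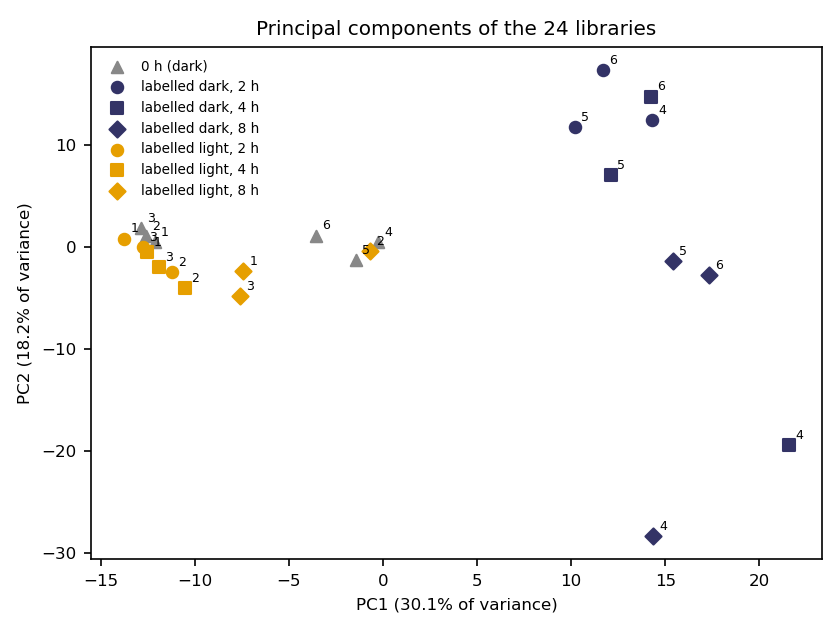
First and second principal components of log2 CPM for the 24 libraries, which hold 30.1% and 18.2% of the variance, with 1 point per library coloured by group. The libraries labelled dark at 2, 4 and 8 h lie at 10.2 or above on the first component, and all other libraries below 0.

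After 2 h most genes of the photosynthetic apparatus were higher in the libraries labelled light than in those labelled dark, many of them several-fold. The light-harvesting antenna genes pufB (1587486 to 1587620 on the chromosome) and pufA (1587069 to 1587284) stood at 6.54-fold (log2 2.71 ± 0.18, SE, n = 3 per group) and 6.53-fold (log2 2.71 ± 0.24). The level of pufB was 944.9 ± 116 CPM (SD, n = 3) with the light label, 144 ± 20.2 CPM (n = 3) with the dark label and 1023 ± 90.3 CPM (n = 6) at 0 h. Of 9 tested reaction centre and light-harvesting genes, 8 were higher and 0 lower, the same counts adjusted over the list alone, with a median log2 of 2.46. Among them were pufM and pufL, the reaction centre core subunits (log2 2.48 ± 0.27 and 2.46 ± 0.27), and pufC at GEMMAAP_RS06575, the reaction centre cytochrome (log2 2.50 ± 0.29). The puh genes of the list were higher by less, with puhA, puhB and puhC at log2 0.78, 0.93 and 1.08. A further locus named pufC, GEMMAAP_RS05925, stood at -0.10 ± 0.19 and did not pass. Of 13 bacteriochlorophyll synthesis genes 10 were higher and 0 lower, again the same adjusted over the list alone. They included the chlorophyllide reductase subunits bchZ (log2 2.17 ± 0.16) and bchY (2.13 ± 0.17) and the magnesium chelatase subunit bchH (2.09 ± 0.21). Haem and tetrapyrrole synthesis had 4 of 11 genes higher and 0 lower, with the same counts adjusted over the list alone, led by hemF (log2 2.23 ± 0.25) and hemG (2.14 ± 0.16), which act on coproporphyrinogen and protoporphyrinogen. ppsR, which encodes a repressor of photosynthesis genes in other bacteria, was 2.05-fold higher (log2 1.03 ± 0.18).

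These genes lie together: of the 33 loci between ppsR and bchI, 35.9 kb from 1560584 to 1596490, 27 were higher and 0 lower at 2 h, with a median log2 of 1.60, and the neighbouring hemG, hemF, hemE and hemA were higher too. The cluster was taken as a set only after its members' values had been seen. The limma camera test of a list against all other genes gave adjusted p = 6.36e-12 for the reaction centre and light-harvesting list, 2.34e-13 for bacteriochlorophyll synthesis and 0.00255 for haem synthesis. With an estimated correlation the adjusted p was 0.0242, 0.00417 and 0.0242.

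**Figure D2:**
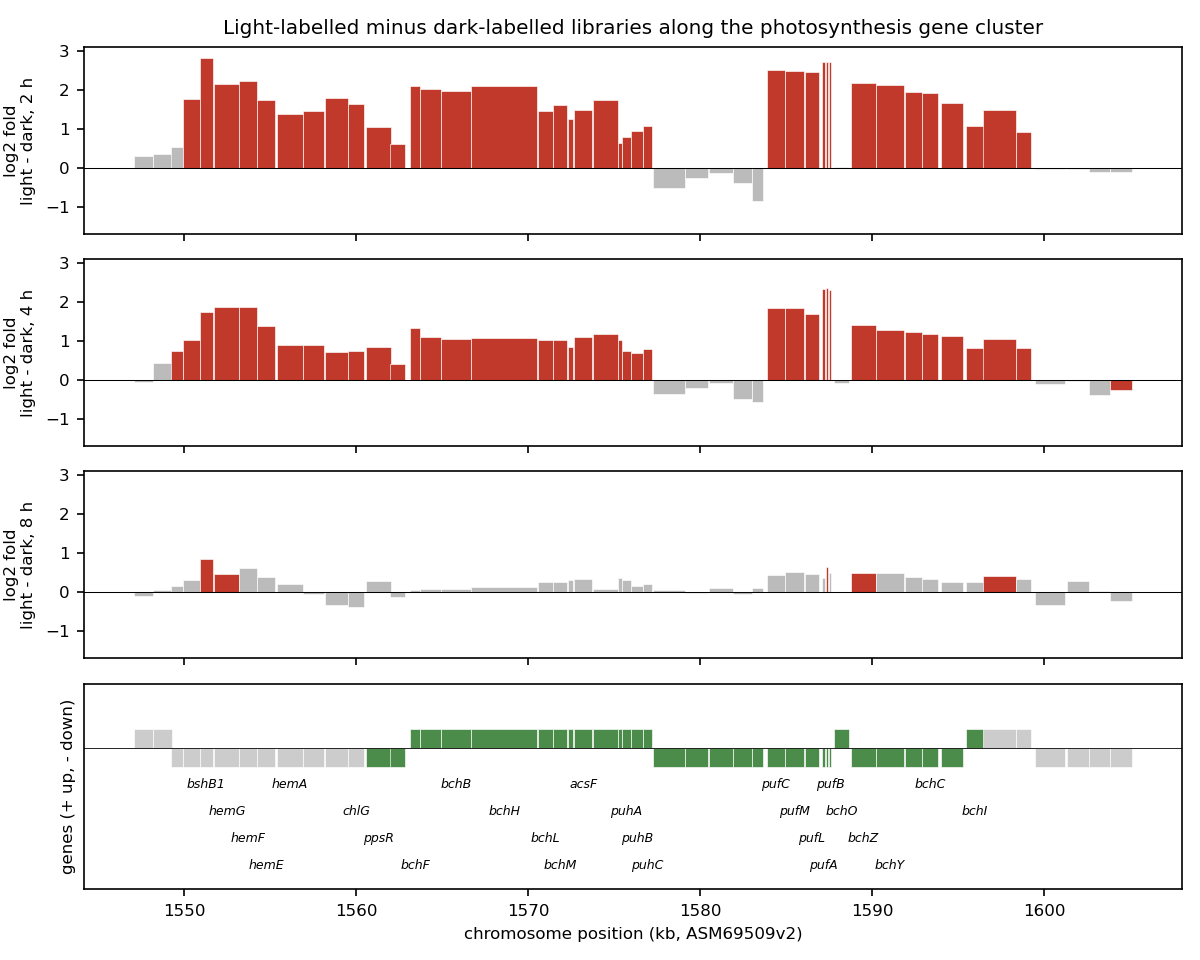
Log2 fold change, libraries labelled light minus those labelled dark, of each locus between ppsR and bchI and of its neighbours, against position on the chromosome, at 2, 4 and 8 h. The median over the 33 loci of the cluster was 1.60 at 2 h, 1.05 at 4 h and 0.27 at 8 h.

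Genes of respiration were also higher with the light label at 2 h. The cytochrome c oxidase subunit genes ctaD and coxB stood at 2.85-fold (log2 1.51 ± 0.15, SE, n = 3 per group) and 2.16-fold (1.11 ± 0.17), with ctaD at 440.5 ± 17.3 CPM (SD) against 154 ± 16.5 CPM. Of 13 NADH dehydrogenase and respiratory chain genes 10 were higher and 0 lower, or 11 and 0 adjusted over the list alone. Of 6 TCA cycle genes 5 were higher and 0 lower under both adjustments, among them the succinyl-CoA synthetase genes sucC (log2 1.19 ± 0.19) and sucD (1.08 ± 0.16). Both lists passed camera (adjusted p = 3.38e-07 and 0.000149), with adjusted p = 0.0492 and 0.0436 with an estimated correlation. At 0 h, before any light, the NADH dehydrogenase and respiratory chain list was already higher in libraries 1 to 3 than in 4 to 6, by a median log2 of 0.38 with 12 of 13 members positive. Camera gave it adjusted p = 6.98e-08, and 0.0204 with an estimated correlation. The TCA cycle list was higher by 0.16 (adjusted p = 0.0107, and 0.294 with an estimated correlation). No single member of either list passed edgeR's quasi-likelihood test at 0 h. sucC nevertheless stood at log2 0.59 ± 0.14 there (SE, n = 3 per set, adjusted p = 0.0839), ctaD at 0.36 ± 0.12 (0.239) and acnA at 0.18 ± 0.13 (0.657).

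Some stress and protein synthesis genes were lower with the light label at 2 h. Of 12 chaperone and protease genes 4 were lower and 0 higher, or 5 and 0 adjusted over the list alone. Among them were dnaK, an Hsp70 chaperone, at 112 ± 9.9 CPM (SD, n = 3) against 232 ± 17.9 CPM (log2 -1.05 ± 0.16), and lon at GEMMAAP_RS14670, an ATP-dependent protease (log2 -0.68 ± 0.18). Of 10 oxidative stress genes 3 were lower and 0 higher, or 5 and 0 adjusted over the list alone, including the catalase-peroxidase gene katG (log2 -0.71 ± 0.13). Of 49 ribosomal protein genes 13 were lower and 0 higher, or 19 and 0 adjusted over the list alone, with a median log2 of -0.46. Of 7 ATP synthase genes 3 were lower and 0 higher, or 6 and 0 adjusted over the list alone. Of 35 translation factor and tRNA ligase genes 5 were lower and 0 higher under both adjustments, including efp and argS (log2 -0.76 ± 0.15 and -0.80 ± 0.17). The translation list also took symbols of other functions, and of the 23 genes left without them 3 were lower. Camera gave adjusted p = 0.00491 for chaperones, 0.00286 for oxidative stress, 1.63e-09 for ribosomal proteins, 0.00239 for ATP synthase and 0.00347 for translation. With an estimated correlation only the chaperone call stayed, at adjusted p = 0.0405, against 0.101, 0.267, 0.267 and 0.0917 for the others in that order. Before any light, 0 h libraries 1 to 3 already stood below 4 to 6 in the chaperone list (median log2 -0.13, 3 of 12 members positive). The same held for oxidative stress (-0.15, 2 of 10 positive). Neither passed camera there (adjusted p = 0.214 and 0.197). Ribosomal proteins, ATP synthase and translation stood at 0.10, -0.01 and 0.04.

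Over all genes, 747 of 3963 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 2 h, 461 higher and 286 lower with the light label. The adjusted p was 7.59e-10 for pufB, 1.55e-07 for ctaD, 7.21e-05 for dnaK and 0.000707 for katG. Scaling by library totals alone gave 728 higher and 52 lower, and a block by sample number, which reads light against dark through the 0 h libraries, left 98 genes. Of 58 named calls 46 passed whichever library was left out, and the count of calls was 354 without dark replicate 1, 366 without dark replicate 3, and 447, 445 and 440 without light replicates 1, 2 and 3.

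After 4 h the photosynthesis genes were still higher with the light label. pufA stood at 5.0-fold (log2 2.32 ± 0.23, SE, n = 3 per group) and pufB at 4.94-fold (log2 2.30 ± 0.18), with hemG at 1.88 ± 0.16, pufM at 1.85 ± 0.26 and bchZ at 1.41 ± 0.15. The reaction centre and light-harvesting list had 8 of 9 genes higher, the bacteriochlorophyll list 10 of 13 and the haem list 5 of 11, with 0 lower in each and the same counts adjusted over the list alone. Their median log2 was 1.70, 1.05 and 0.42, and 27 of the 33 cluster loci were higher. The respiratory chain list had 12 of 13 genes higher under both adjustments and the TCA cycle list 4 of 6, or 5 adjusted over the list alone. Among these ctaD stood at log2 1.43 ± 0.15, sucC at 1.23 ± 0.19 and the aconitase gene acnA at 1.04 ± 0.14. Lower genes at 4 h included rocF, an arginase gene (log2 -1.24 ± 0.15, at 206 ± 10.2 CPM against 489 ± 61.0 CPM, SD), and rocD, which encodes ornithine aminotransferase (-0.98 ± 0.12). Of 12 chaperone genes 4 and of 10 oxidative stress genes 2 were lower under both adjustments, with dnaK at -0.96 ± 0.16 and katG at -0.76 ± 0.13. The ribosomal protein list had 1 of 49 genes lower, or 0 adjusted over the list alone, and a median log2 of 0.05 (camera adjusted p = 0.441). Its mean log2 relative to all other genes was 0.17, and became -0.19 (adjusted p = 0.00159) without dark replicate 1, the library apart on the second component, and 0.48 (adjusted p = 1.73e-06) without dark replicate 3.

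At 4 h camera gave adjusted p = 2.27e-09 for reaction centre and light harvesting, 7.78e-09 for bacteriochlorophyll synthesis, 0.00518 for haem synthesis, 2.06e-10 for the respiratory chain and 0.00052 for the TCA cycle. With an estimated correlation the adjusted p was 0.0420, 0.0227, 0.0227, 0.0227 and 0.0617, so that the TCA cycle call was lost. The calls for chaperones (adjusted p = 0.0297), oxidative stress (0.0298) and DNA replication (0.0298, with 1 of 15 genes lower under both adjustments) were lost with an estimated correlation, at adjusted p = 0.0639, 0.249 and 0.249. They were lost too without dark replicate 3 (adjusted p = 0.0902, 0.157 and 0.110), and the DNA replication call without dark replicate 1 (0.0770). Over all genes 698 passed edgeR's quasi-likelihood test, 438 higher and 260 lower, with adjusted p = 1.2e-08 for pufB and 5.53e-06 for rocF. Library totals alone gave 359 higher and 66 lower, and the block by sample number left 120. Without light replicate 3 the count was 434, and a fit to the libraries of that time alone called fewer still. Of 54 named calls 41 passed whichever library was left out.

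After 8 h the photosynthesis lists no longer passed. pufB stood at log2 0.50 ± 0.17 (SE, n = 3 per group) with adjusted p = 0.0505 in edgeR's quasi-likelihood test, and its level was 857 ± 50.9 CPM (SD) with the light label against 605 ± 68.5 CPM with the dark label. The reaction centre and light-harvesting list had 0 of 9 genes past the threshold (median log2 0.35, camera adjusted p = 0.0781), although this list passed without light replicate 2 (0.0390) or without dark replicate 3 (0.00296). In the bacteriochlorophyll list 1 of 13 genes was higher under both adjustments (median 0.25, adjusted p = 0.0854, and 0.00848 without dark replicate 3). The respiratory chain list still had 9 of 13 genes higher and 0 lower, or 12 and 0 adjusted over the list alone (median 0.59), among them ctaD (log2 0.75 ± 0.14) and nuoF at GEMMAAP_RS12220, an NADH dehydrogenase subunit (0.59 ± 0.12). Its camera adjusted p was 6.82e-08, against adjusted p = 0.174 with an estimated correlation. Higher genes that passed whichever library was left out also included tssE, tssF and tssH of the type VI secretion apparatus (log2 0.87 ± 0.13, 0.86 ± 0.12 and 0.83 ± 0.17), acnA (0.71 ± 0.13) and the glyceraldehyde-3-phosphate dehydrogenase gene gap (0.60 ± 0.12). rocF and rocD were again lower, at -1.10 ± 0.15 and -0.87 ± 0.12.

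Several of the most extreme genes at 8 h rested on 1 library. epsC, at log2 1.67 ± 0.42, had 103 CPM in light replicate 2 against 18.7 and 18.5 CPM in the other light libraries, and stood at 0.39 (adjusted p = 0.153 in edgeR's quasi-likelihood test) without it. The ribosomal protein gene rpsP (log2 -1.28 ± 0.32), the ribosome maturation gene rimM (-1.16 ± 0.32), the secretion gene gspG (-1.03 ± 0.27) and the DNA repair gene mutM (-0.86 ± 0.23) stood at -0.56, -0.67, -0.33 and -0.36 without dark replicate 1 (adjusted p = 0.151, 0.172, 0.216 and 0.189). rpsP had 309 CPM in that library against 95.6 and 112 CPM in the other dark libraries. The ribosomal protein list, with 1 of 49 genes lower under both adjustments but a median log2 of 0.37, passed camera (adjusted p = 0.00022), with adjusted p = 0.810 with an estimated correlation and 0.0906 without dark replicate 1.

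At 8 h 524 genes passed edgeR's quasi-likelihood test, 254 higher and 270 lower with the light label, with adjusted p = 0.000288 for rocF and 0.00306 for ctaD. Library totals alone gave 377 higher and 46 lower, the block by sample number left 3, and a fit to the 6 libraries of that time alone called 0 genes. Without light replicate 1 the count was 150 and without light replicate 3 it was 192, and 16 of 33 named calls passed whichever library was left out.

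**Figure D3:**
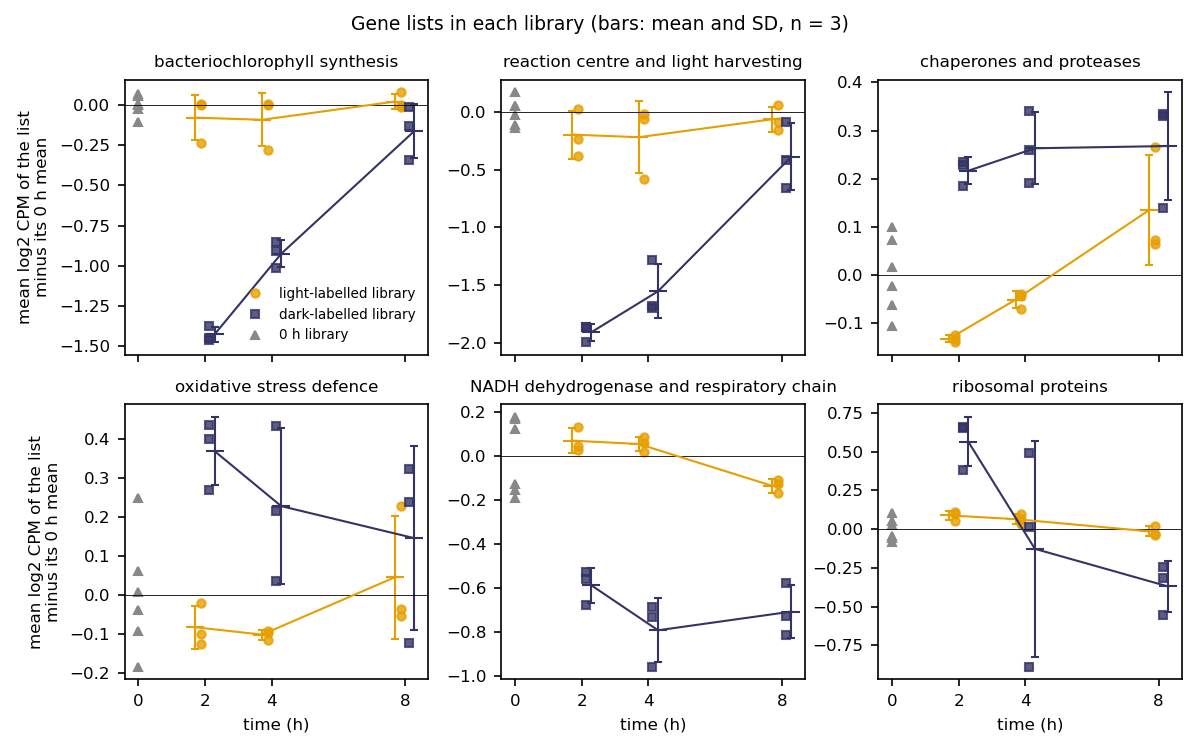
Mean log2 CPM over the members of 6 gene lists relative to the 0 h libraries, per library (points) and as group mean with SD (lines and bars), against time in hours for the libraries labelled light and dark. The reaction centre and light-harvesting list stands at -1.91 ± 0.07 (SD, n = 3) with the dark label and -0.20 ± 0.21 with the light label at 2 h.

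Other fixed lists showed few calls with the light label. DNA repair had 2 genes higher and 2 lower of 22 at both 2 and 4 h under both adjustments, with recD (log2 0.91 ± 0.22, SE, n = 3 per group) and recO (-0.63 ± 0.14) among those past the threshold at 2 h, and 0 at 8 h. The level of recD was 180 CPM with the light label and 96.1 CPM with the dark label at 2 h, but already ranged from 90.3 to 171 CPM at 0 h. Its change with the dark label at 2 h against 0 h was log2 -0.48, and -0.13 with a block by sample number. The SOS genes recA and lexA did not pass at any time. DNA replication and cell division had 2 of 15 genes lower at 2 h under both adjustments (camera adjusted p = 0.0501) and 0 at 8 h. Fatty acid synthesis had 1 of 8 genes higher at 2 and at 4 h, and glycolysis and gluconeogenesis 1 of 9 at 4 and at 8 h. Motility, with 16 genes, and iron-sulphur cluster assembly, with 5, had 0 past edgeR's threshold at any of the 3 times. ATP synthase had 0 at 4 and 8 h, and chaperones 0 at 8 h. Translation had 4 of 35 genes lower at 4 h, and 1 higher and 2 lower at 8 h. The haem list had 1 of 11 genes higher at 8 h, or 3 higher and 1 lower adjusted over the list alone, the TCA cycle list 2 of 6 higher, or 3, and the oxidative stress list 1 of 10 lower. The lists with 1 tested member held ppsR, higher at 2 and 4 h, the sigma factor gene rpoN (log2 0.31 ± 0.10 at 2 h) and the iron transporter gene feoB (-0.49 ± 0.11 at 2 h). The rpoN call was lost in edgeR's quasi-likelihood test whichever library was left out at 2 h, with adjusted p up to 0.134 without dark replicate 1. Of the 3 transcripts on the ribosomal and transfer RNA list, 0 passed at 2 and 8 h and 1 was lower at 4 h.

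Tested directly, the light minus dark difference was smaller at 8 h than at the earlier times for several photosynthesis genes, although the calls between 4 and 8 h did not hold in every fit. From 4 to 8 h it fell by 1.97 ± 0.32 on the log2 scale for pufA, by 1.80 ± 0.24 for pufB, by 1.41 ± 0.22 for hemG and by 1.27 for bchF (SE, n = 3 per group). From 2 to 8 h it fell by 2.36 ± 0.32 for pufA, 2.21 ± 0.24 for pufB and 2.07 ± 0.39 for pufC at GEMMAAP_RS06575. In all 7 genes passed edgeR's quasi-likelihood test between 4 and 8 h, with adjusted p = 0.000564 for pufB and 0.00275 for pufA, and each of the 7 was smaller at 8 h. Between 2 and 8 h 48 genes passed, 10 with a higher and 38 with a lower difference at 8 h. Between 2 and 4 h edgeR called 0 genes, with 151 at an unadjusted p under 0.05 and 0 by DESeq2. Between 4 and 8 h a fit to the groups compared alone called 0 genes, and library totals alone 3. Other divisions of the same libraries, with times exchanged within each label, were fitted too. As many genes were called in 22 of 100 of them between 4 and 8 h and in 9 of 100 between 2 and 8 h. The counts also depended on single libraries. Between 4 and 8 h the count was 18 without dark 8 h replicate 1 and 11 without light 4 h replicate 2, and between 2 and 8 h it was 161 without dark 8 h replicate 3 and 31 without dark 2 h replicate 3. Of the genes higher with the light label at 2 and at 4 h 311 were shared, where independent lists would share 51.0, and of those lower 130 against 18.8. At 4 and 8 h 185 and 95 were shared against 28.1 and 17.7, and no gene was called in opposite directions at any pair of times. The value for independent lists makes no allowance for differences between the culture sets that last over the times, and 82.4% of 720 genes called at 2 h outside the cluster had the same sign between the sets at 0 h.

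**Figure D4:**
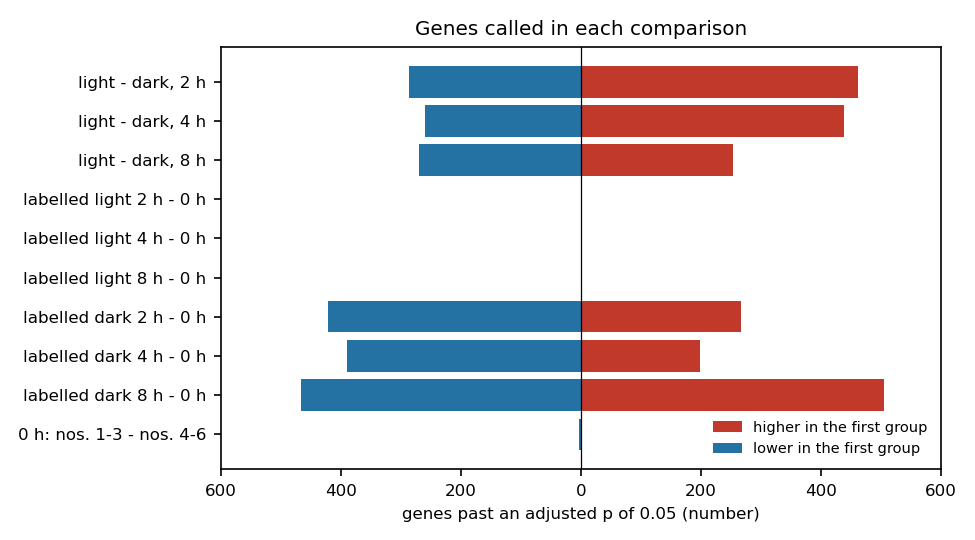
Number of genes past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in each comparison, higher to the right and lower to the left of the zero line. The libraries labelled light differ from those labelled dark by 747, 698 and 524 genes at 2, 4 and 8 h, and from the 0 h libraries by 0 at each time.

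Set against the 0 h libraries, the photosynthesis genes did not pass the test in the libraries labelled light, and many of them were several-fold lower in those labelled dark. With the dark label at 2 h, pufA was 8.15-fold lower (log2 -3.03 ± 0.23, SE, n = 3 against 6), pufB 7.08-fold (-2.82 ± 0.17), hemG 4.57-fold (-2.19 ± 0.15) and ctaD 2.61-fold (-1.39 ± 0.13), while dnaK (0.72 ± 0.13) and katG (0.58 ± 0.11) were higher. At 4 h pufA stood at -2.70 ± 0.22, hemG at -2.03 ± 0.15 and ctaD at -1.38 ± 0.13. The reaction centre list had 8 of 9 genes lower at both times, the bacteriochlorophyll list 10 of 13, and the cluster 27 of its 33 loci. Of 13 respiratory chain genes 10 were lower at 2 h, or 4 with a block by sample number, and 12 at 4 h. Of 49 ribosomal protein genes 24 were higher at 2 h, or 42 adjusted over the list alone (camera adjusted p = 4.51e-16, and adjusted p = 0.133 with an estimated correlation). In the libraries labelled light pufA was at -0.32 ± 0.19, pufB at -0.11 ± 0.15, hemG at -0.05 ± 0.13 and ctaD at 0.13 ± 0.12 at 2 h. edgeR's quasi-likelihood test called 689 genes for the dark label at 2 h, 267 higher and 422 lower, and 588 at 4 h, 198 higher and 390 lower. It called 0 for the light label at 2, 4 and 8 h, with 98, 126 and 144 genes at an unadjusted p under 0.05, and DESeq2 called 0 at each time, while the block by sample number gave 32 for the light label at 8 h. With that block 368 genes stayed for the dark label at 4 h. These comparisons were chosen after the positions of the groups had been seen. With library totals alone the dark label gave 63 higher and 585 lower genes at 2 h and 63 and 334 at 4 h. The count at 2 h was 315 without dark replicate 1 and 327 without dark replicate 3, and for the light label at 8 h it was 1 without light replicate 2 or without light replicate 3.

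Some fixed lists shifted in the libraries labelled light against 0 h by small amounts, with 0 members past edgeR's test. The reaction centre and light-harvesting list was lower at 2 h (median log2 -0.15, camera adjusted p = 0.00972) and at 4 h (-0.24, 0.0053), and motility was lower at 2, 4 and 8 h (-0.39, -0.47 and -0.40, with 0.00972, 0.00028 and 0.00667). Ribosomal proteins were higher at 2 h (0.09, 0.0319), and at 8 h chaperones were higher (0.12, 0.00858) and the respiratory chain and TCA cycle lists lower (-0.13 and -0.14, with 0.00858 and 0.0198). With an estimated correlation each call was lost, at adjusted p = 0.849 and 0.866 for the reaction centre list, 0.875, 0.866 and 0.942 for motility, 0.906 for ribosomal proteins, and 0.0957, 0.767 and 0.599 for the lists at 8 h. With library totals alone ribosomal proteins (adjusted p = 0.0766) and the TCA cycle (0.229) were lost. All but motility at 4 h were lost without 1 library as well: without light replicate 2 at 2 h (adjusted p = 0.274, 0.207 and 0.179 for reaction centre, motility and ribosomal proteins), light replicate 2 at 4 h (0.695, reaction centre), and at 8 h light replicate 2 (0.259 for chaperones, 0.197 for the TCA cycle) or light replicate 3 (0.101 for the respiratory chain, 0.369 for motility). Leaving out a 0 h library also ended the calls for motility (replicate 3 or 5) and ribosomal proteins (5 or 6) at 2 h, and for the respiratory chain (1, 2 or 3) and the TCA cycle (2 or 3) at 8 h.

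The change of the libraries labelled dark from 0 h to 8 h was a planned comparison, on how far the dark cultures moved with further growth. The 0 h group also holds libraries 1 to 3, whose numbers recur only in the light series. At 0 h these stood above libraries 4 to 6 in the respiratory chain list (median log2 0.38), so a fall of that list can hold a difference between the sets. After 8 h the lower genes included nuoK at GEMMAAP_RS09065, an NADH dehydrogenase subunit (log2 -1.06 ± 0.17, SE, n = 3 against 6), tssH (-1.0 ± 0.15), acnA (-0.89 ± 0.12) and ctaD (-0.81 ± 0.13), with pufB at -0.76 ± 0.15. The higher ones included rocF, 2.52-fold (log2 1.33 ± 0.12), gspG (1.22 ± 0.22, but 0.52 without dark 8 h replicate 1), rocD (1.04 ± 0.10) and dnaK (0.87 ± 0.13). Of 13 respiratory chain genes 12 were lower and 0 higher under both adjustments (camera adjusted p = 4.27e-10, and adjusted p = 0.0763 with an estimated correlation). Of 6 TCA cycle genes 4 were lower under both (0.0118, and adjusted p = 0.355 with an estimated correlation). The reaction centre list had 4 of 9 genes lower under both (0.0118, and adjusted p = 0.576 with an estimated correlation), and this call was lost without dark 8 h replicate 1 (0.156). Motility had 5 of 16 genes lower, or 9 adjusted over the list alone (median log2 -1.0, adjusted p = 0.00435, and adjusted p = 0.576 with an estimated correlation), and lost its call without dark 8 h replicate 3 (0.0661). Chaperones had 5 of 12 genes higher under both (0.0434, and adjusted p = 0.251 with an estimated correlation), a call lost without dark 0 h replicate 1 (0.0520), dark 8 h replicate 2 (0.0932) or dark 8 h replicate 3 (0.108). The ribosomal protein list had 1 gene higher and 3 lower, or 1 and 0 adjusted over the list alone, and a median log2 of -0.37 (0.000133, and adjusted p = 0.576 with an estimated correlation). In all 972 genes passed edgeR's quasi-likelihood test, 505 higher and 467 lower, with adjusted p = 9.08e-07 for rocF. Library totals alone gave 178 higher and 485 lower, the block by sample number left 383, and the count was 597 without dark 8 h replicate 1.

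At 0 h, where all 6 libraries were taken before any light, libraries 1 to 3 were set against libraries 4 to 6 as the background of the light and dark series. The 4 genes that passed edgeR's quasi-likelihood test were all lower in libraries 1 to 3 and were named after their values were seen: soxC at GEMMAAP_RS02050, a sulphur oxidation gene by its symbol (log2 -1.54 ± 0.29, SE, n = 3 per set), GEMMAAP_RS02055 (-1.37), GEMMAAP_RS10595 (-1.27) and GEMMAAP_RS00315 (-0.80 ± 0.14), each with adjusted p = 0.0304. None of the photosynthesis genes was among them, and the median log2 was 0.005 over the bacteriochlorophyll list, -0.02 over the reaction centre list and 0.001 over the cluster. Another 5 genes passed with library totals alone, all higher and none shared with the 4. The count was 0 in edgeR whichever of the 6 libraries was left out, while 453 genes had an unadjusted p under 0.05 and DESeq2 called 49. A fit to the 6 libraries alone called 126, and leaving out the 3 libraries apart, none of them of 0 h, gave 177.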

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

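Chosen only after the results were seen were the comparisons with 0 h other than that of dark at 8 h, the tests of an exchange of labels, of the culture sets and of growth, the tests of a later dark library and of epsC, and the counts of other splits. The first pattern is that the libraries labelled light stayed near the 0 h libraries while those labelled dark moved away, with 0 genes called for the light label at 2 h against 0 h and 689 for the dark label (edgeR, and DESeq2 also called 0 for the light label; 98 genes had an unadjusted p under 0.05). A difference between the 2 sets of cultures before the light is argued against for the photosynthesis cluster, whose median log2 difference at 0 h between libraries 1 to 3 and 4 to 6 was 0.00129 (quartiles -0.10 to 0.06), against 1.60 between light and dark at 2 h. Over 720 genes called at 2 h outside the cluster, the slope of the 0 h difference on the 2 h difference was 0.248 (0.216 to 0.272 with each 0 h library left out), with 82.4% of them of the same sign at 0 h. A culture difference may thus be part of it there, but at its 0 h size not the whole. A difference between the sets that grew after 0 h, in or outside the cluster, cannot be told apart from light, since light and dark libraries share no sample number. A growth effect that moves dark cultures steadily away from 0 h is argued against for the cluster by its direction. In the libraries labelled dark its medians were -1.67, -1.15 and -0.33 at the 3 times, and the median over its loci of the 8 h minus 2 h difference was 1.33, back towards 0 h. A passing change with growth that returns by 8 h would give the same values and was not tested. Steady growth cannot be told apart over 561 genes outside the cluster called for the dark label at 4 h. Their median moved by -0.014 (-0.07 to 0.03 with each library left out), and 270 of them lay farther from 0 h at 8 h than at 2 h. An exchange of the light and dark labels would give these values and stays open as a hypothesis, the more so as light represses pigment genes in many aerobic phototrophic bacteria, and so does a biological response of the dark cultures after 0 h, for which the design has no separate test.

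The second pattern is light 8 h replicate 2, which stood apart from its group on the first principal component (-0.69 against -7.43 and -7.61) and carried the epsC call. A library of a later time of the dark series in its place is argued against by its position between light (0) and dark (1) over the 698 genes called at 4 h, 0.309, where the libraries labelled dark lay between 0.616 and 1.08 and the other libraries labelled light between -0.01 and 0.11. For epsC a mixture with dark 8 h replicate 2 and a 0 h library are argued against, since its 103 CPM is 5.53 times the highest of the libraries mixed and 4.96 times the highest at 0 h, where the other 23 libraries differ by at most 2.16 times. A mixture with dark 8 h replicate 2 is among the explanations that may account for the rest. The mixed share was 0.552 (95% bootstrap interval 0.347 to 0.878) on 33 genes chosen to mark sample number 5, that of dark 8 h replicate 2. It was 0.297 (0.211 to 0.391) on the genes called at 4 h. The 2 intervals overlap only from 0.347 to 0.391. A 0 h library in its place cannot be told apart beyond epsC, since a median of 59 genes (52 to 144) lay outside the range of 5 libraries at 0 h, against 1 to 85 for a 0 h library held out. On the position above, the 0 h libraries 4 to 6 lay at 0.271 to 0.302, near its 0.309, and the library nearest to it was dark 0 h replicate 5. No biological explanation was tested for this library.

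The test of the difference between times picked out 7 genes between 4 and 8 h and 48 between 2 and 8 h. Between 4 and 8 h the light minus dark difference was lower at 8 h by log2 values of -1.97 for pufA, -1.80 for pufB, -1.72 for GEMMAAP_RS06595, which lies between them, -1.41 for hemG and -1.27 for bchF. Between 2 and 8 h it was lower by -2.36 for pufA, -2.21 for pufB, -2.07 for pufC at GEMMAAP_RS06575, -2.06 for GEMMAAP_RS06595, -2.05 for bchF, -2.00 for pufL, -1.97 for pufM and -1.96 for bchH. It was also lower by -1.90 for bchB, -1.68 for bchZ, -1.67 for hemG, -1.65 for bchY, -1.60 for hemF, -1.36 for bchM, -1.34 for hemE, -1.18 for hemA, -1.18 for bchL, -1.16 for acsF and -0.81 for bchI. For GEMMAAP_RS01440, whose level was lower with the light label, it was higher by 1.66.

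Among the 6 libraries at 0 h, 4 of 95 values tested had 1 library far from the others, where chance picks out about 1 in 20 groups. bchL had 87.7 CPM in replicate 5, with the next lowest at 100.4 CPM. groL had 309 CPM in replicate 1, with the next lowest at 390.2 CPM. lon at GEMMAAP_RS14670 had 226 CPM in replicate 5, with the next highest at 161 CPM. fdhF had 8.76 CPM in replicate 4, with the next lowest at 14.1 CPM.

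Other splits of the same libraries were fitted in the same way. For light against dark the 10 splits of 3 and 3 libraries are too few for a share under 0.05, and 1 of 10, the real one, gave as many calls each time: 747 at 2 h with 0 in the highest other split, 698 at 4 h with 1, and 524 at 8 h with 17. For the 0 h libraries the 10 splits are likewise too few, with 4 genes in the real split and 0 in the highest other. With free exchange of the libraries, 1 of 84 splits, the real one, gave as many calls for dark at 8 h against 0 h (972 genes, 333 in the highest other). The same held for dark at 4 h (588 and 239, 1 of 84). Sample numbers 4 to 6 recur in both groups, however, with 1 of 3 such pairs correlated above 0.1 at 8 h and 2 of 3 at 4 h. If a number marks 1 culture, the splits that part the pairs are too few for a share under 0.05, so chance was not excluded. For dark at 2 h 1 of 84 splits, the real one, gave as many (689, highest other 151), but of the 8 splits that part the 3 pairs of sample numbers, too few for a share under 0.05, the highest other gave 1; the other splits set both libraries of at least 1 number on the same side. Where the real split gave 0 genes the count of splits says nothing of chance, since all 84 of 84 (light label against 0 h) and 100 of 100 (difference between 2 and 4 h, highest other 5) give at least 0. The highest other split for the light label gave 75, 39 and 9 genes at 2, 4 and 8 h, and points to a structure of the samples, since at 2 and 4 h it set 0 h libraries 4 to 6 against all others. For the differences between times, the splits exchanged times within each label without regard to sample number, and chance could not be excluded: 22 of 100 gave as many between 4 and 8 h (7, highest other 364) and 9 of 100 between 2 and 8 h (48, highest other 82). The 3 dark pairs of 4 and 8 h with the same sample number were all correlated above 0.1 (0.427 to 0.527). Free exchange may therefore not hold for them, and splits that part such pairs were not counted apart here. Of the 8 others as large between 2 and 8 h, all kept the real times of 1 label and so its change with time, and the 73 splits that mixed the times of both labels gave at most 41 genes. Between 4 and 8 h 11 of 73 such splits gave as many, among them that with 364 genes, which points to a structure of the samples. It set dark 4 h replicate 1 and dark 8 h replicate 1, both of sample number 4 and apart on the second component, on the same side.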

How the results depend on the processing

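Leaving out the 3 libraries apart, and the comparisons with 0 h other than that of dark at 8 h, were chosen only after seeing the data. Of 145 named calls, 145 kept their direction and stayed past the threshold with DESeq2, 142 with RLE scaling, 110 with library totals alone, 100 with only the groups compared, 137 without the 3 libraries apart and 103 whichever library was left out. Of 20 list calls 19 stayed with fry, 19 with library totals, 20 with a prior count of 0.5, 19 without the 3 libraries apart, 16 whichever library was left out and 10 with an estimated correlation. Library totals alone moved the median log2 of all genes by 0.23, 0.12 and 0.24 for light minus dark at 2, 4 and 8 h, by -0.12 and 0.14 for the differences from 2 to 4 h and from 4 to 8 h, by -0.15 for dark at 8 h against 0 h, by 0.17 for the 0 h sets, and by -0.17 and -0.10 for the dark label at 2 and 4 h against 0 h. The list tests, which compare a list with all other genes, turned no direction under it. Sampling depth differed by library, and changes of 1.5-fold were recovered for 18 of 67 simulated genes at 2 h.

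The numbers in the titles were not taken to pair the samples, except for dark at 2 h against 0 h. The correlation of deviations between light and dark libraries of 1 time with the same replicate number was -0.06 to 0.24 over 9 pairs, above 0.1 in 3, and over the 36 pairs that share a sample number from 1 to 6 it was -0.24 to 0.56, above 0.1 in 22. Between neighbouring times all 9 such pairs of the dark series were above 0.1 (0.127 to 0.527), and 5 of 9 of the light series (-0.163 to 0.558). The best match of a library lay in its own sample number for 14 of 24 libraries, so not for every one. With a replicate block by replicate number the counts were 844, 759 and 586 for light minus dark at 2, 4 and 8 h, and 2 in place of 0 for the light label at 8 h against 0 h. With a block by sample number they were 98, 120 and 3. It gave 73 for the difference between 2 and 8 h, 383 for dark at 8 h and 368 for dark at 4 h against 0 h, 32 for light at 8 h against 0 h, and 73 named calls stayed. In that fit a sample number occurs with light or with dark only, so light against dark is read through the 0 h libraries. lexA at 4 h turned to 0.0038 with the first block and 0.038 with the second, and recA at 8 h to -0.052 with the second. None of these genes passed in any of these fits. For dark at 2 h against 0 h this block gave 470 genes, kept 53 of 63 calls among the named genes, and let the lists of DNA repair and of iron-sulphur cluster assembly pass camera (adjusted p = 0.0221 and 0.0342, against 0.106 and 0.0941), with no other list call changed.

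Counts that moved by over 1.5 times under other settings were as follows, and where no construction is named the cause was not tested. With library totals alone 425 genes passed at 4 h, 3 for 4 to 8 h and 27 for 2 to 8 h. With only the groups compared the counts were 1204, 314 and 0 for light minus dark at 2, 4 and 8 h, 0 for 4 to 8 h and 126 for the 0 h sets. DESeq2 gave 19 for 4 to 8 h, 90 for 2 to 8 h and 49 for the 0 h sets. A log2 threshold of 1, stricter by construction, left 147, 145 and 84 for light minus dark, 143 for dark at 8 h, 87 for dark at 2 h and 93 for dark at 4 h against 0 h. Without the 3 libraries apart the counts were 1265 at 2 h, 6 for 2 to 4 h, 14 for 4 to 8 h, 83 for 2 to 8 h, 177 for the 0 h sets and 1110 for dark at 2 h against 0 h.

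Leaving out 1 library gave 354 to 675 calls at 2 h, 434 to 739 at 4 h and 150 to 649 at 8 h. It gave 5 to 18 for 4 to 8 h, 31 to 161 for 2 to 8 h, 597 to 1083 for dark at 8 h, 0 for the 0 h sets, 0 to 1 for light at 8 h and 315 to 722 for dark at 2 h against 0 h, and 0 for 2 to 4 h. Values that turned sign, none of them of a gene past the threshold, were these. With library totals pufC at GEMMAAP_RS05925 stood at 0.16 at 2 h and 0.020 at 8 h, recA at 0.13 at 2 h, and lexA at 0.13 at 4 h and 0.17 at 8 h. Without the 3 libraries apart pufC at GEMMAAP_RS05925 stood at 0.0242 and lexA at 0.0493 at 4 h. At 8 h hemA stood at -0.019, bchF at -0.013, bchB at -0.15, bchH at -0.12 and acsF at -0.0086. With 1 library left out lexA ranged from -0.11 to 0.13 at 2 h, -0.13 to 0.0493 at 4 h and -0.16 to 0.10 at 8 h. recA ranged from -0.25 to 0.031, -0.061 to 0.19 and -0.083 to 0.17, and pufC at GEMMAAP_RS05925 from -0.36 to 0.0241 at 4 h. At 8 h bchF ranged from -0.026 to 0.12, bchB from -0.18 to 0.33 and bchH from -0.11 to 0.35. The mean of the ribosomal protein list relative to all other genes, 0.17 for light minus dark at 4 h, stood at -0.19 without the 3 libraries apart and ranged from -0.19 to 0.48 with 1 library left out. For the dark label at 4 h against 0 h it was -0.088, stood at 0.27 without the 3 libraries apart and ranged from -0.40 to 0.27, the ends being dark 4 h replicates 1 and 3 left out.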

Other observations

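The gene families below and their tests were chosen only after the type VI secretion genes had been seen among the named genes. A type VI secretion system is a contractile apparatus that delivers proteins into neighbouring cells. Its tss genes, 9 of them between 4592239 and 4608773 on the chromosome, were higher in the libraries labelled light than in those labelled dark at each time: 6 of 9 at 2 h (median log2 0.44), 7 at 4 h (0.77) and 7 at 8 h (0.69), with 0 lower. At 4 h the sheath gene tssC stood at log2 0.78, tssF at 0.99 and the ATPase gene tssH at 1.08. Against 0 h the libraries labelled dark had 8 of 9 lower at 2 h (7 with a block by sample number) and at 4 h and 7 lower at 8 h, while those labelled light had 0 past edgeR's quasi-likelihood test at 2, 4 and 8 h. Among 25 families of at least 5 symbols that share their first 3 letters, camera gave tss adjusted p = 0.000318, 4.09e-07 and 1.15e-06 at 2, 4 and 8 h, against adjusted p = 0.152, 0.0374 and 0.119 with an estimated correlation. Its direction was the same with library totals alone. At 0 h, before any light, its median difference between libraries 1 to 3 and 4 to 6 was 0.04 (camera adjusted p = 0.715), with tssH at 0.34.

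Some genes of the arg family, most of them of arginine synthesis, and of the sec family of protein export were lower with the light label. Of 8 arg genes 2 were lower at 2 h, argC (log2 -0.70) and argS, and 4 at 4 h, argB, argC, argG and argS, in edgeR's quasi-likelihood test, with 0 higher. The family passed camera at both times (adjusted p = 0.00439 and 0.00778) and not at 8 h (0.0930), and with an estimated correlation the adjusted p was 0.215 and 0.239 at 2 and 4 h. argS is a tRNA ligase gene and argR a regulator gene, so that of the other 6 genes 1 passed at 2 h and 3 at 4 h. Of 6 sec genes of the protein export channel 3 were lower at 2 h, secA, secD and secG (log2 -0.56, -0.47 and -0.42), with camera adjusted p = 0.00386 and adjusted p = 0.215 with an estimated correlation. The sec family did not pass camera at 4 h (adjusted p = 0.126) or 8 h (0.957). At 0 h the arg family was already lower in libraries 1 to 3 than in 4 to 6, by a median log2 of -0.15 (adjusted p = 0.00349, and adjusted p = 0.196 with an estimated correlation), and the sec family stood at 0.13 (0.788). Both directions at 2 h were the same with library totals alone.

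Several loci without a symbol differed as much as the photosynthesis genes, and are given here because of their size. GEMMAAP_RS01445 (325001 to 325411) was at 228 ± 43.7 CPM (SD, n = 3) with the light label and 2245 ± 168 CPM with the dark label at 2 h, against 256 ± 84.1 CPM (n = 6) at 0 h, a log2 difference of -3.30 ± 0.28 (SE) between light and dark, and its neighbour GEMMAAP_RS01440 stood at -2.89 ± 0.29. The run from GEMMAAP_RS08125 to GEMMAAP_RS08145 was lower at 2 h by log2 values of -1.52 to -2.36, and the run from GEMMAAP_RS12135 to GEMMAAP_RS12150 was higher, by 1.65 to 1.90. All of these loci kept their direction at 4 and at 8 h, although GEMMAAP_RS08145 did not pass edgeR's quasi-likelihood test at 8 h (log2 -0.90 ± 0.33). At 0 h their differences between libraries 1 to 3 and 4 to 6 were -0.52 to 0.37, with adjusted p of 0.423 or more.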
